A study of Homo sapiens with 4 samples.

How the data were processed

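Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out in H9 cells, an established human embryonic stem cell line grown without feeder cells. Per the labels' protocols, cells were crosslinked with 1% paraformaldehyde and chromatin was sonicated to an average of 500 bp. Per the same protocols, immunoprecipitated DNA was amplified with 18 PCR cycles and fragments of 150 to 300 bp were cut from a gel, which corresponds to inserts of 50 to 200 nt. Antibodies were against Oct4, a transcription factor of pluripotent cells, or were nonspecific immunoglobulin (IgG). There were 4 libraries: 1 from IgG, 2 sequencing runs of Oct4 biological replicate 1, and 1 from Oct4 biological replicate 2. The runs of replicate 1 were added together, so n = 2 Oct4 replicates throughout.

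Each deposited file lists aligned read positions with the strand as their sign, and holds no counts or peaks made by the authors. Per the file headers, reads were aligned with Bowtie to hg18 with options -e 70, -k 2, -m 2 and -n 2, and with a seed of 26 bases (IgG, run 1) or 36 bases (run 2, replicate 2). The Bowtie version was not given in the sources used here. The first section of a file holds reads with 1 placement and the second reads with 2 placements, both of which are listed. Reads with more placements were absent because of -m 2, so sequence repeated more than that cannot show enrichment. The file headers put IgG and run 1 on 1 flow cell, and run 2 and replicate 2 on a further one each. Comparisons of run 1 with IgG are therefore within a flow cell, and those of replicate 2 with IgG are not. IgG and run 1 also share the seed length. Sequence with 1 placement at 36 bases but not at 26 can hold reads of run 2 and replicate 2 and lack IgG reads. How far this affects the called regions was not tested.

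Positions were taken as leftmost bases counted from 0 on both strands. The leftmost base was checked on the runs of replicate 1. Their reverse-strand positions were shared most often at an offset of 10 bp (18390 shared positions against a median of 1456 at other offsets). Forward-strand positions were shared most often at 0 bp (18352 against 1457). Counting from 0 was not checked, since these offsets would be the same for positions counted from 1. The 5' ends shared by both runs were 4.02% of those of run 1, against 0.364% shared by run 1 and replicate 2. Part of the reads of replicate 1 are thus copies of the same fragments seen in both runs, and removing them was an added alternative.

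Main analysis used reads with 1 placement, with 1 read kept per position and strand in each library. Each 5' end was moved 60 bp in the 3' direction. Reads were counted in 300-bp windows every 100 bp, and 17696095 windows with at least 1 read of any library were tested. A one-sided Poisson test compared each window with the largest of the library mean per tested window and the IgG density in 1000, 5000 and 10000 bp around it, scaled to library totals. Windows with a Benjamini-Hochberg q under 0.01 within 300 bp of each other were joined. Consensus regions were regions of both replicates overlapping by at least 1 bp, with the union as bounds. Chance overlap was measured with 100 shuffles of the replicate 2 regions over tested windows, and with 100 moves of each by 10 to 100 kb.

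Enrichment of a region was its reads per 1000000 reads used (RPM) over that of IgG, with IgG set to a floor of 3 counts per region where it held fewer. Exact binomial tests compared the counts of each Oct4 replicate with IgG (one-sided) and of both replicates with each other (two-sided, scaled to reads in consensus regions), with Benjamini-Hochberg adjustment over regions. These regions were chosen for enrichment on the same reads, so the p-values against IgG describe counting error and are not independent evidence. There was 1 IgG library, so tests against it compare libraries and not conditions. Shares of reads carry exact Clopper-Pearson 95% intervals, and ratios carry exact binomial 95% intervals. Reads had no molecular identifiers, so intervals and floors cover counting error only. Correlations used log2(RPM + 1). An alternative test of enrichment used limma on log2(RPM + 1), which assumes that the lone IgG library varies like the Oct4 replicates.

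The caller was tested on simulated libraries. With no planted sites and the real IgG reads as control, 3 simulated pairs of replicates gave at most 2 regions in 1 replicate and at most 1 in both. Simulated reads followed the IgG density in 10000 bp with counting error alone. The expected count of the caller includes that density, so few calls were possible, and biases of the real Oct4 libraries were not simulated. Of 200 planted sites per size, 12% were found in both replicates at 10-fold over the mean window, 66% at 15-fold, 89.5% at 20-fold and 99% at 30-fold, and none at 5-fold. Weak sites were thus mostly missed in this simulation. Planted sites were far fewer than the regions called in the real libraries, which makes the Benjamini-Hochberg limit stricter. The shares therefore do not measure how many weak sites the real calls missed.

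Regions were named by a rule fixed before the data were examined: the 20 consensus regions with the largest smaller fold of both replicates. They are given by hg18 coordinates (counted from 1) alone, since no hg18 sequence or annotation was used here. Planned analyses of gene positions, gene lists and motifs were not run for the same reason. Alternatives covered duplicate removal, the shift, window size, thresholds, the IgG background, depth, overlap, left-out runs and replicates, limma, bin size and scaling. Further ones, chosen after the data were seen, were reads with 2 placements, duplicates across runs, a regional background, separate parts of the IgG reads, levels over IgG reads not used for calling, 5' ends not moved, and leaving out chromosomes Y and M. Software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.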

Results

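Oct4 occupancy was mapped in H9 human embryonic stem cells with 3 Oct4 ChIP-seq libraries and 1 IgG library as background. Reads with 1 placement in hg18 numbered 3732939 in IgG, 3475837 in run 1 and 3615352 in run 2 of Oct4 replicate 1, and 3912305 in Oct4 replicate 2. After repeats of a position were removed, 3507529, 3222845, 3448207 and 3810535 reads were used. Repeats were 6.04% of IgG reads, 7.28% and 4.62% of the reads of run 1 and run 2, and 2.60% of replicate 2 reads.

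The first comparison asked where Oct4 reads exceeded IgG reads in both biological replicates. Regions called in both replicates made 7868 consensus regions, which covered 4961200 bp and had a median width of 600 bp. These regions held 3.46% ± 0.056 (SD, n = 2) of Oct4 reads against 0.560% of IgG reads (95% interval 0.552% to 0.568%), a ratio of 6.18. With no IgG in the expected count the regions covered 12433600 bp, the shares were 6.70% and 2.09%, and the ratio was 3.20. Without run 2 of replicate 1 the Oct4 share was 2.24% over 2491200 bp (ratio 7.56), and at q under 0.0001 it was 1.964% over 2055800 bp (7.73). Run 1, on the same flow cell and with the same seed length as IgG, held 3.34% of its reads there (3.32% to 3.36%). Run 1 lay above IgG in 7844 of these regions, with a median fold of 3.265. The regions were chosen for enrichment on these reads. Levels are given as reads per 1000000 reads used (RPM). Over its whole width, a region lay above IgG in both replicates in 7864 of the 7868. The other 4 were on chromosome 2 at 132731501 to 132732000, chromosome 17 at 28173601 to 28174200 and at 38755701 to 38756700, and chromosome 20 at 26136801 to 26137300, with smaller folds of 0.847 to 0.995.

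**Figure D1:**
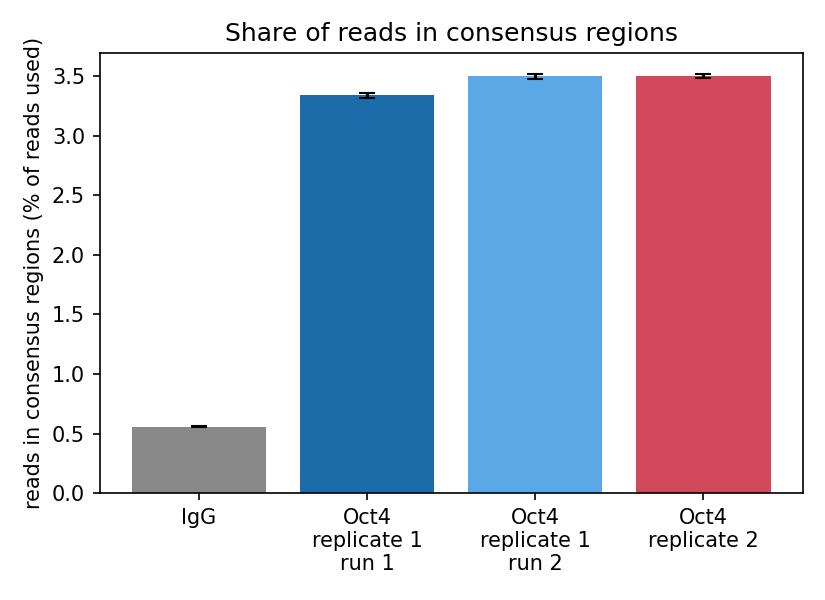
Share of the reads used that lay in the 7868 consensus regions, in percent, for each of the 4 libraries. Bars are the shares and error bars exact 95% binomial intervals, which cover counting error only. The Oct4 libraries lie between 3.34% and 3.50%, and IgG lies at 0.560%.

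Replicate 1 alone gave 25841 regions and replicate 2 gave 12889. Of these, 7880 regions of replicate 1 (30.5%) and 7897 of replicate 2 (61.3%) fell in consensus regions. Shuffled replicate 2 regions overlapped replicate 1 regions 147.8 times on average (highest of 100 shuffles, 185), and regions moved by 10 to 100 kb did so 171.1 times (highest 202). Both lists used the same IgG reads, and simulated replicates without sites gave at most 1 common region against them. Those replicates were drawn from the IgG density in 10 kb, which the caller also uses, so few calls were possible. They cannot show how many common regions come from biases of the real Oct4 libraries. With a separate random part of the IgG reads for each replicate, chosen after the data were seen, there were 7132 consensus regions, and 6573 of the 7868 overlapped them. Both parts come from 1 library, so part of the excess over chance may come from that shared control. The number of consensus regions was 4491 at equal depth, 3538 at q under 0.0001, 15906 with no IgG in the expected count, and 5103 or 4257 without run 1 or run 2 of replicate 1. All Oct4 libraries added together and called once gave 37023 regions.

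The median of the smaller fold of both replicates was 3.15. It was at least 3 in 4264 regions, at least 5 in 1294, at least 10 in 167 and at least 20 in 9. IgG held 0 reads in 1083 regions and fewer than 3 in 4893 (62.2%), where the floor lowered the fold. In 3460 regions (44.0%) both replicates passed the exact binomial test against IgG at an adjusted p under 0.01, and a single limma fit of both replicates against IgG gave 6246. With IgG measured over 5000 bp around each region, 7860 regions passed and the median smaller fold was 8.60. The caller had already required an excess over the IgG density in 5000 bp, so that count was favoured beforehand.

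With IgG counted inside the region, the largest smaller fold lay on chromosome 3 at 195012701 to 195013900 (hg18). It held 218 reads of replicate 1 (105 in run 1, 113 in run 2), 113 of replicate 2 and 3 of IgG. This corresponds to 31.2 ± 2.14 RPM (SD, n = 2) in Oct4 against 0.855 RPM in IgG, 38.2-fold in replicate 1 (95% interval 12.9 to 187) and 34.7-fold in replicate 2 (11.6 to 171). With IgG over 5000 bp its smaller fold was 31.0, and the highest of the 20 named regions was then 73.6, on chromosome 1 at 198283601 to 198284600. Chromosome 15 at 29158801 to 29159600 followed with 26.6 ± 6.21 RPM against 0.855 RPM, 25.9-fold in replicate 1 (8.70 to 127) and 36.2-fold in replicate 2 (12.1 to 178). A second region on the same chromosome, 29385801 to 29386500, held 22.3 ± 2.19 RPM against 1.14 RPM.

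**Figure D2:**
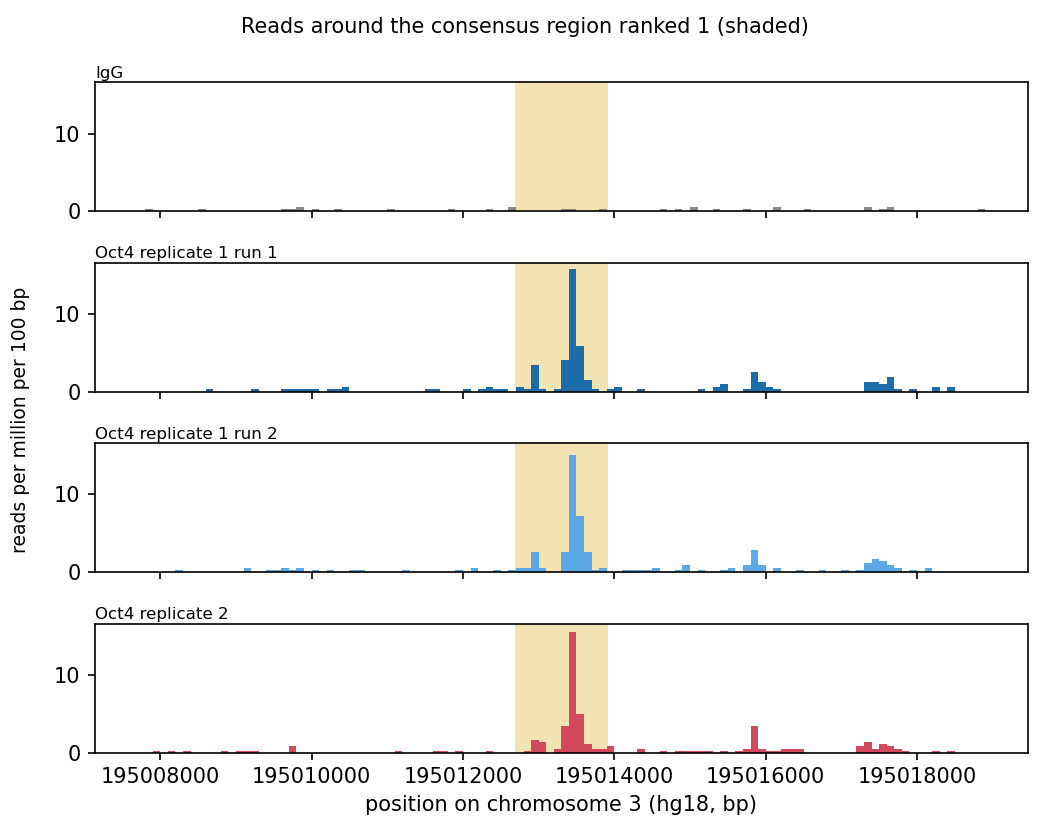
RPM per 100 bp around the consensus region ranked 1 on chromosome 3 (hg18), with the region from 195012701 to 195013900 shaded, in each of the 4 libraries. The Oct4 libraries share a narrow maximum inside the region, where IgG holds 3 reads.

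Chromosome 1 held 4 of the 20 named regions. The region at 15583201 to 15584100 had the highest level among all 20, 46.8 ± 5.29 RPM against 1.71 RPM in IgG, 29.5-fold in replicate 1 (13.4 to 81.0) and 25.2-fold in replicate 2 (11.3 to 69.6). The region at 43246701 to 43247500 held 21.98 ± 0.285 RPM, that at 198283601 to 198284600 held 21.5 ± 0.736 RPM, and that at 224153301 to 224154300 held 20.9 ± 1.99 RPM. IgG held 2, 2 and 3 reads in them.

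Of the other named regions, chromosome 3 at 32796801 to 32798400 held 36.6 ± 3.59 RPM against 1.71 RPM in IgG. Chromosome 5 at 138883401 to 138884400 held 26.3 ± 2.87 RPM against 1.14 RPM, and chromosome 7 at 137578601 to 137579400 held 21.7 ± 5.40 RPM against 0.570 RPM. Chromosome 13 at 27437901 to 27439400 held 21.1 ± 2.47 RPM, and chromosome 14 at 60638101 to 60638900 held 17.2 ± 0.525 RPM. On chromosome X, 149821401 to 149822100 held 21.6 ± 0.245 RPM against 1.14 RPM. Chromosome 12 at 69014701 to 69015300 held 106 and 60 Oct4 reads and no IgG read, at least 18.6-fold and at least 18.4-fold higher with IgG set to the floor of 3 counts (exact 95% lower limits without the floor 14.8 and 14.5). Chromosome 12 at 117903201 to 117903900 held 17.3 ± 1.82 RPM against 0.855 RPM.

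The remaining named regions lay on chromosomes 16, 2, 11 and 9. Chromosome 16 at 30596601 to 30597500 held 17.1 ± 1.86 RPM with 1 IgG read, and at 54872701 to 54873500 it held 15.9 ± 1.69 RPM with 3 IgG reads. Chromosome 2 at 5783301 to 5784300 held 18.1 ± 4.43 RPM, chromosome 11 at 116085701 to 116086300 held 15.8 ± 1.09 RPM, and chromosome 9 at 91482301 to 91483600 held 20.2 ± 0.418 RPM. Smaller folds of all 20 regions ranged from 17.2 to 34.7, and from 13.5 to 73.6 with IgG over 5000 bp. In each of the 20, the replicates differed by less than 1.5 times, and the highest adjusted p of the exact binomial tests against IgG was 6.3e-11. Ranking by the smaller fold on the same reads favours both outcomes.

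**Figure D3:**
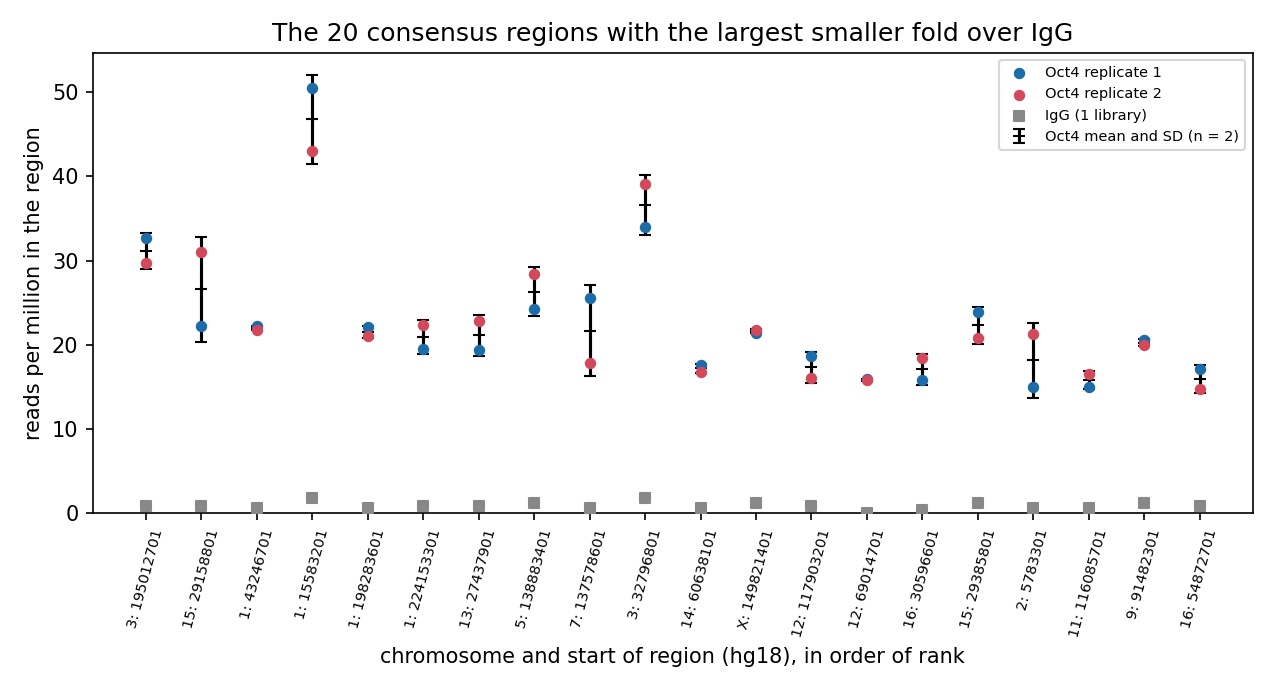
RPM in the 20 named regions, in order of rank, for Oct4 replicate 1, Oct4 replicate 2 and the 1 IgG library. Black marks are the mean and SD of both Oct4 replicates (n = 2). IgG lies below 2 RPM in every named region, and the Oct4 means lie between 15.8 and 46.8 RPM.

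Reads of the forward and reverse strands were displaced around the consensus regions. The most frequent distance from a forward to a reverse 5' end was 122 bp in run 1, 123 bp in run 2 and 120 bp in replicate 2, and 24 bp in IgG. In the mean profile of the regions, forward ends peaked 160, 140 and 80 bp left of reverse ends in these Oct4 libraries, and 120 bp left in IgG. Regions had been called and centred with 5' ends moved by 60 bp. Without that move, an alternative chosen after the data were seen, the displacement was 140 bp in each Oct4 library and 120 bp in IgG. The most frequent distance was then 140, 123 and 116 bp in run 1, run 2 and replicate 2, and 24 bp in IgG. The close match of 122, 123 and 120 bp may thus come partly from the move. Forward 5' ends peaked at 142.7, 155.2 and 151.1 RPM per 20 bp and 1000 regions in run 1, run 2 and replicate 2. In IgG they peaked at 16.4, above 7.07 at the edge of the window, so IgG reads were also denser at these regions.

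**Figure D4:**
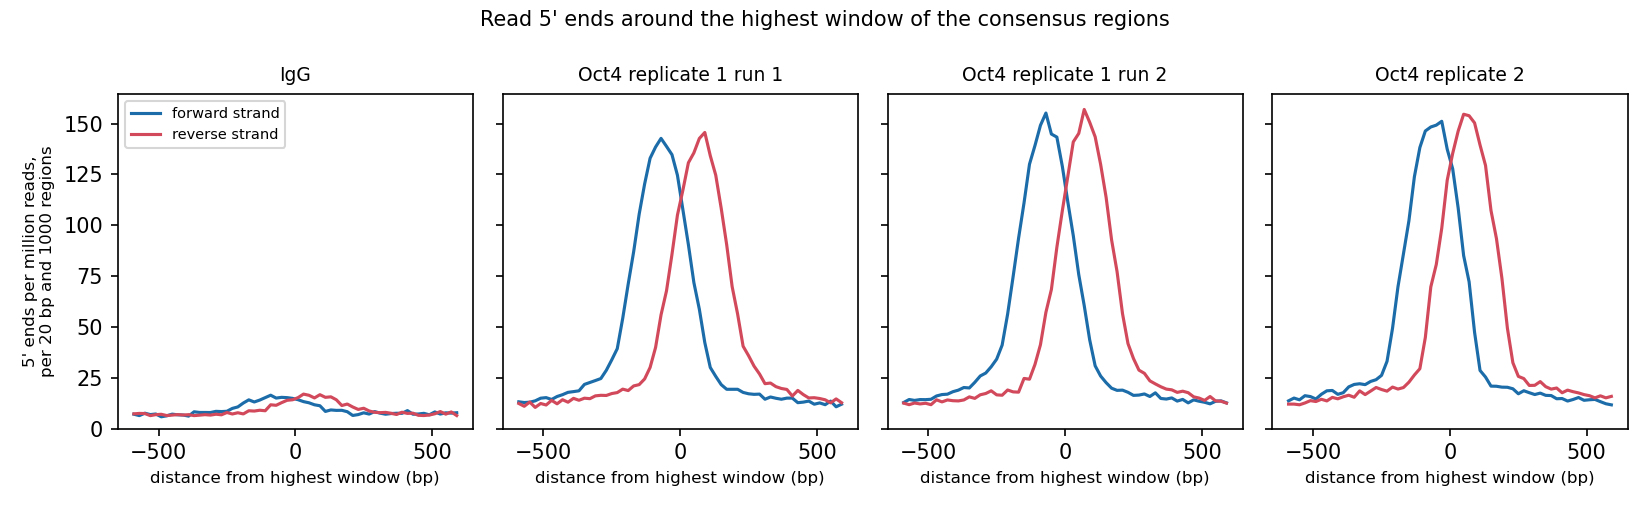
Read 5' ends, as RPM per 20 bp and 1000 regions, at each distance in bp from the highest window of the 7868 consensus regions, in each of the 4 libraries. Lines are the forward and the reverse strand. Forward ends peak left of reverse ends in all 4 libraries, by 80 to 160 bp in Oct4 and 120 bp in IgG. Forward peaks are 142.7 to 155.2 in Oct4 and 16.4 in IgG.

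The next comparison set the spread between biological replicates against that between runs of 1 library. Consensus regions had to be called in both replicates, which favours similar levels. Of them, 82 (1.04%) passed the two-sided exact binomial test at an adjusted p under 0.01, 73 higher in replicate 1 and 9 higher in replicate 2. None differed between run 1 and run 2 by the same exact test, where 264 had an unadjusted p under 0.05 (722 between replicates), and 1 differed when scaled to library totals. The SD of the log2 ratio across regions was 0.56 between replicates, where counting alone gave 0.51, and 0.64 between runs, where counting alone gave 0.64. With run 2 or run 1 alone as replicate 1, 42 or 51 regions differed. Among regions called in run 2 or replicate 2 alone, a choice that favours different levels, 212 of 14038 (1.51%) differed between them.

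The region most clearly higher in replicate 1 lay on chromosome 2 at 188876401 to 188877200, with 24.4 RPM in replicate 1 (84 and 79 reads in run 1 and run 2), 4.72 RPM in replicate 2 and 1.14 RPM in IgG (exact binomial test, adjusted p = 2.3e-12). Chromosome 1 at 181639001 to 181639900 held 18.1 against 2.89 RPM, and chromosome 4 at 113792701 to 113793400 held 14.99 against 2.10 RPM. Of the 9 regions higher in replicate 2, 6 had an IgG density over 5 times the IgG mean, and of the 73 higher in replicate 1 none had. Chromosome 2 at 132745901 to 132748400 held 39.1 RPM in replicate 1, 77.2 in replicate 2 and 30.2 in IgG, and chromosome 18 at 97901 to 99600 held 17.7, 43.3 and 15.4 RPM. These examples were chosen by adjusted p after their values were seen.

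Over the windows tested for all libraries, run 1 alone gave 9065 regions and run 2 gave 11199, and 61.9% of run 1 regions overlapped those of run 2. Of the run 1 regions, 46.7% overlapped those of replicate 2. In all regions of replicate 1, replicate 2 held 4.08 times the RPM of the IgG reads also used to call them. In regions of replicate 2, replicate 1 held 5.18 times. With regions called against a random part of the IgG reads and levels set over the other part, chosen after the data were seen, these ratios were 3.24 (95% interval 3.20 to 3.28) and 4.01 (3.95 to 4.08).

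Across 7868 consensus regions, which are not independent replicates, Pearson's r of log2(RPM + 1) was 0.783 between runs, 0.745 between biological replicates, and 0.434, 0.432 and 0.556 between IgG and run 1, run 2 and replicate 2. Spearman's rho was 0.734 between runs and 0.686 between replicates. At equal depth r was 0.778 between runs and 0.679 between replicates. Across 10-kb bins, r was 0.780 between runs and 0.776 between replicates, and at equal depth 0.771 and 0.716. In these bins IgG correlated with replicate 1 at 0.703 and replicate 2 at 0.585, and at equal depth at 0.643 and 0.562.

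The last comparison was by chromosome. Among chromosomes 1 to 22 and X, consensus regions were densest on 19 and 17, with 339 regions, 2.16 times the number expected from tested windows (95% interval 1.94 to 2.40), and 421 regions, 1.84 times (1.67 to 2.02). Chromosomes 22 and 16 held 1.52 and 1.35 times the expected number. Of the same chromosomes, X held the lowest density, 143 regions or 0.419 times (0.354 to 0.493), followed by chromosomes 21, 4 and 13 with 0.595, 0.685 and 0.702 times. Chromosome Y, outside that ranking, held 8 regions, 2.41 times the expected number (1.04 to 4.76), which did not pass (exact binomial test, adjusted p = 0.0593). The median smaller fold of these 8 regions was 2.04. In 6 of them the IgG density was over 5 times the IgG mean, so they are not taken as evidence of Oct4 occupancy of chromosome Y. Outside all called regions, the replicate 2 share of reads over IgG was also above 1 on chromosomes 19, 17, 22 and 16, at 1.67, 1.34, 1.59 and 1.29, which the expected count of the caller did not include. With the density of the own library in 50 kb as a further limit, chosen after the data were seen, these chromosomes held 1.70, 1.68, 1.37 and 1.36 times the expected number, and X held 0.467 times. By exact binomial tests with an adjusted p under 0.01, 8 chromosomes held more and 7 held fewer regions than expected.

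Total reads also differed by chromosome. The chromosome 19 share of reads over that of IgG was 1.17 in run 1, on the same flow cell, and 1.67 in replicate 2 (1.66 to 1.69). On chromosome 22 replicate 2 reached 1.52, and on chromosome 4 it held 0.779 and on chromosome 13 0.809 times the IgG share. Mitochondrial reads (chromosome M) of replicate 2 were 0.338 times the IgG share (0.322 to 0.355). By exact binomial tests, 22 of 25 chromosomes differed from IgG in replicate 1 and 23 in replicate 2.

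**Figure D5:**
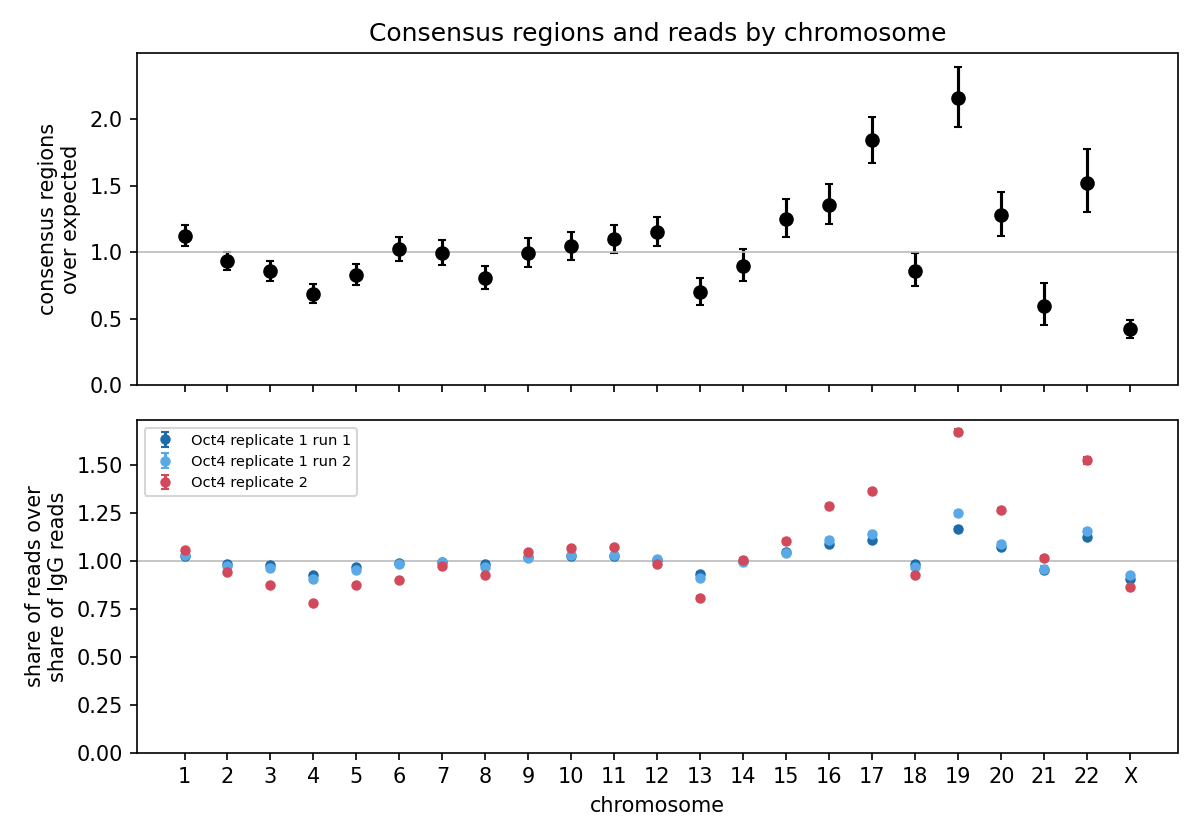
Upper panel, consensus regions per chromosome over the number expected from tested windows. Lower panel, share of each Oct4 library's reads over the IgG share. Error bars are exact 95% binomial intervals. Chromosomes Y and M are not drawn. Of those drawn, 19, 17 and 22 lie highest in the upper panel, and on chromosome 19 the lower panel shows 1.67 in replicate 2 and 1.17 in run 1.

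With the libraries exchanged, IgG was enriched over Oct4 replicate 1 in 19 regions and over replicate 2 in 37, of which 5 and 3 lay on chromosome M. The Oct4 direction gave 25841 and 12889 regions. The exchanged call does not count calls that come from biases of an Oct4 library. With all reads kept they were 116 and 253, and they were 35 and 70 with at most 2 reads per position.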

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

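The search among reads with 2 placements was chosen after the data were seen. These reads are outside the measurements above, which used reads with 1 placement. They gave 1813 regions in Oct4 replicate 1 and 1727 in replicate 2, of which 680 were common, against 36 and 74 regions with IgG over Oct4. Of reads with 1 or 2 placements, those with 2 were 7.95% in IgG and 7.43% in run 1, aligned with a 26-base seed. They were 4.38% in run 2 and 4.83% in replicate 2, aligned with a 36-base seed. IgG is thus no matched control for run 2 and replicate 2 here, and the effect on these calls was not tested. Since both placements of a read were counted, a single occupied site can appear as 2 regions, and 628 of the 680 did not overlap a consensus region. The highest smaller fold, 21.2, was on chromosome 6 at 167613401 to 167614200, with 87 placements in replicate 1, 46 in replicate 2 and 3 in IgG. Chromosome 6 at 167559001 to 167559900 had the same Oct4 placements and 4 in IgG, so these reads cannot be assigned to either copy. Chromosome 14 at 76503701 to 76505400 held 86, 88 and 1 placements. Positions 671001 to 672800 on X and on Y had identical placements, 64, 29 and 2, and so did 380401 to 381600, with 80, 27 and 1. No explanation of these regions was tested.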

How the results depend on the processing

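Alternatives were fixed before the data were examined except 2-placement reads, duplicates across runs, regional background, separate IgG parts, IgG reads not used for calling, leaving out Y and M, 5' ends not moved, equal-depth enrichment and some left-out libraries, which were chosen afterwards. Consensus regions, 7868 as reported, numbered 3538 at q under 0.0001, 15906 without IgG, 4491 at equal depth and 37023 with all Oct4 reads called once; left-out runs or replicates gave 4257 to 25841. Replicate 1 regions numbered 13009 at q under 0.0001, 40809 without IgG and 11296 at equal depth, and 9078 to 11457 with a run left out, where windows without reads of the remaining libraries were not tested. Replicate 2 regions numbered 5109 at q under 0.0001, 21587 at q under 0.05 and 23205 without IgG. These settings change depth, threshold, control or the need for a call in both replicates, and so move the counts by construction. IgG regions over replicates 1 and 2 numbered 116 and 253 with all reads, 35 and 70 with at most 2 reads per position, 12 and 21 at q under 0.0001, and 329 each without a control; 500-bp windows gave 11 over replicate 1, and left-out runs 22 to 29. The cause was not tested.

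The share of Oct4 reads in consensus regions was 3.76% with all reads, 3.71% with at most 2 per position, 3.39% with a 100-bp shift, 2.51% and 4.66% with 200-bp and 500-bp windows, 1.964% and 4.65% at q under 0.0001 and 0.05, 6.70% without IgG, 2.35% at equal depth and 3.00% with 50% overlap. Added alternatives gave 3.53% with 2-placement reads, 3.33% with duplicates removed across runs, 3.06% with the regional background and 3.26% with separate IgG parts. Left-out libraries gave 2.24% to 3.50%. The ratio to the IgG share ran from 3.20 without IgG (12433600 bp called) to 7.73 at q under 0.0001 (2055800 bp). The cause was not tested.

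Regions past the test in both replicates numbered 7860 with IgG over 5000 bp, which the call itself favoured, and a single limma fit of both gave 6246. The median smaller fold was 8.60 with IgG over 5000 bp, 3 at equal depth and 3.07 with either run left out. With a replicate left out, only the median fold of the other remained, 3.51 in replicate 1 and 3.68 in replicate 2. Pearson's r across bins was 0.438 between runs and 0.492 between replicates in 1-kb bins, where counts are lower, 0.771 and 0.716 at equal depth, and 0.718 to 0.746 between replicates with a run left out. Regions differing between replicates numbered 42 to 51 with a run left out. In the 20 named regions, all 140 values under 7 alternatives stayed above IgG and past the exact binomial test. These regions were chosen for the largest smaller folds on the same reads, which favoured that outcome beforehand. Leaving out a replicate, moreover, cannot lower the smaller fold. The order changed, with smaller folds of 13.5 to 73.6 with IgG over 5000 bp. Gene positions, gene lists and motifs were not run. No paired analysis was possible because the labels give 1 IgG library. Depth limits the search: replicate 1 gave 25841 regions as reported and 11296 at equal depth. In simulation 12% of sites at 10-fold the mean window and 66% at 15-fold were found in both replicates. Far fewer sites were planted than regions were called in the real libraries, so these shares do not carry over to the real calls.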

Other observations

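The tests of read length, antibody, depth and counting noise were chosen after their results were seen, and the other tests before; moving regions by 50 to 500 kb and weighting regions equally were added afterwards. Consensus regions lay close together more often than chance gave. Of neighbouring pairs, 414 lay within 5 kb of each other, against 129.7 with shuffled regions (highest of 100 shuffles, 158) and 199.4 when each region was moved by 50 to 500 kb (highest 228). Within 10 kb there were 670 pairs against 237.4 shuffled (highest 271).

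Replicate 2 reads lay more on chromosomes 19, 22, 17, 16 and 20 than IgG reads. Reads in called regions did not account for it, since outside all called regions and 5 kb around them the chromosome 19 ratio was 1.67 (95% interval 1.65 to 1.69). Enrichment too weak to be called stays in those reads, so the test cannot exclude it. Longer reads did not either: run 2 over run 1 of the same library was 1.07 on chromosome 19 (1.06 to 1.08). In replicate 1 the Oct4 antibody fell short of that ratio, because run 1 over IgG on the same flow cell was 1.17 (1.15 to 1.18). Run 1 covers the immunoprecipitation of replicate 1 only, so it cannot exclude a stronger antibody effect in replicate 2. What stays open is enrichment too weak to be called, or a difference in culture, chromatin, immunoprecipitation, library preparation or sequencing run of replicate 2. That includes GC content, which was not tested because no hg18 sequence was used here.

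More regions were called in replicate 1 alone than in replicate 2 alone, by 3.60 times, and at equal depth the ratio was 1.08, so greater depth may account for that excess. At equal depth, 6796 and 6300 regions were called in replicate 1 alone and in replicate 2 alone. Counting noise near the threshold is a candidate explanation for many, since 61.9% of run 1 regions overlapped those of run 2 of the same library. A difference between the replicates stays undecided: 1.51% of regions called in run 2 or replicate 2 alone differed between them by the exact binomial test, and 0.0111% for both runs, but this sets 1 library of each replicate against technical noise. Regional background of replicate 2 also stays undecided: a limit from its own density in 50 kb ended the call of 38.1% of regions of replicate 2 alone, between the bounds set beforehand. The longer seed of replicate 2 than of IgG was not tested as an explanation.

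In 506 consensus regions the IgG density was over 5 times its library mean, and none of the 20 named regions was among them. Point-source binding as their main signal stays undecided. The most frequent distance between strands was 34 bp in them, also with each region weighted equally. That lies near the 36-base seed of run 2 and replicate 2, as the 24 bp of IgG in all consensus regions lies near its 26-base seed. A distance set by the read length can hide one set by binding, so the test cannot decide. Repeats collapsed in or missing from the assembly are a candidate source for part of them, as 4.74% lay within 200 kb of a stretch of at least 100 kb without reads, 5.37 times the share of the other regions. That concerns 24 of the 506 regions, and the rest stays open. No biological explanation of these regions other than point-source binding was tested.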
